A study of Rattus norvegicus with 36 samples.

How the data were processed

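Liver RNA of male Sprague Dawley rats was measured on 36 one-colour Affymetrix 3′ expression arrays for rat, 1 array per sample. Per the labels' protocols, the rats were 7 weeks old at the start and received the flame retardant hexachlorocyclopentadienyl-dibromocyclooctane (HCDBCO) or corn oil alone by gavage, in 5 ml per kg body weight, once a day on 5 days. Tissue was taken 1 day after the last dose. Per the same protocols, RNA with an integrity number of at least 7 was used, 100 ng was amplified, and 12.5 µg of labelled RNA was hybridised for 16 h.

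The values analysed were the authors' processed values, 1 per probe set and array. Per the submitters' processing notes, they were made with RMA, which corrects background, normalises between arrays and summarises the probes of a probe set, and with the affy package; the notes give no versions. The deposited values were taken as log2 values, the scale on which RMA reports; they ran from 1.94 to 14.7. Raw intensities were not analysed here, so the base of the logarithm was not checked against them. The medians of the 36 arrays lay between 5.06 and 5.16.

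The table held 31099 probe sets. The 57 control probe sets were left out, which left 31042 for testing. Gene names came from the probe annotation supplied for the array, whose symbols were set against a RefSeq gene table of assembly GRCr8 through Entrez gene IDs, for names only. Of the probe sets tested, 20826 had 1 gene symbol, 436 had several and 9780 had none listed. The Entrez ID of 20758 was in the RefSeq table and that of 68 was not, and no symbol changed. No gene was named from a probe set with several. These annotations covered 14217 genes. A gene with several probe sets was represented by the one with the highest mean over all samples, and for a difference given, the value of another probe set is added where it has the other sign, passed or failed the FDR differently, or was clearly closer to or farther from 0. Some genes, among them members of the fixed lists, are not reported here.

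Groups and replicate numbers were taken from the sample titles. The design text states that vehicle was set against each dose at an FDR of 5%, with another R package. That package was not used here; a one-way design was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 6 group means over all 36 samples and no covariate. The contrasts were each dose against vehicle, 541 against 54.1 mg/kg, a linear trend over the dose order with scores 0 to 5, and limma's moderated F-test of any difference among the 6 groups. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 31042 probe sets, at an FDR of 5%. Unless stated otherwise, every adjusted p for a gene is from limma, every group has n = 6, and every ± beside a difference is limma's standard error. The labels give no animal numbers, so the p-values measure the spread between these samples. They name no batch, array date or RNA batch either, so none could be entered.

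Gene lists, the rule for naming genes and the alternatives given last were fixed before the data were examined. There were 38 lists, 25 of responses and pathways and 13 of cell types or liver zones; 586 of their 676 listed members were measured. Each list was tested with limma's camera on 1 probe set per gene, with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Its p-values were adjusted over the 38 lists within a contrast. Members were counted past the FDR over all probe sets and adjusted over the list alone. Exact permutation tests of each list's mean per sample, over the 924 ways to allot 12 samples to vehicle and a dose, were added after the results had been seen.

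The rule for naming genes took, per dose, the 10 largest rises and the 10 largest falls among genes past the FDR whose 6 treated samples all lay on 1 side of the vehicle mean. From each list it took up to 4 members with the smallest p at 541 mg/kg, or 2 for a list with no member past the FDR. It also took a few named genes at every dose, of which those measured by a probe set with 1 symbol are given, and, for 541 against 54.1 mg/kg, the 5 largest rises and 5 largest falls past the FDR. Other features named were chosen after their values had been seen, and are marked so.

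The procedure was tested on simulated data, drawn for the 31042 probe sets from the vehicle means and the residual spread, with 200 probe sets changed at 541 mg/kg in each of 5 rounds. It recovered 19.1% of those changed by 0.25 on the log2 scale, 87.2% of those changed by 0.5 and 98.5% of those changed by 1, and on average 4.35% of its calls for that comparison were false. The noise was normal and drawn independently for each probe set, without deviations shared between genes or arrays. The rates therefore hold for that setting and may be too favourable for the real arrays. The number of arrays limits the precision: the median standard error of a difference between groups was 0.0799 on the log2 scale.

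The alternatives tried were an unmoderated test, moderation with an intensity trend, a filter on dim probe sets, centring of each array on its median, cyclic loess between arrays, array quality weights, the replicate number as a block, 1 probe set per gene, fits of the groups compared alone, another dose score and leaving out each sample in turn. Figures were drawn with matplotlib 3.10.9.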

Results

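Gene expression was measured in 36 rat liver samples in 6 groups of 6, given HCDBCO at 541, 54.1, 5.41, 0.54 or 0.05 mg/kg per day or corn oil alone as vehicle. HCDBCO is a halogenated flame retardant. The question put by the design is which transcripts each dose changes relative to vehicle. The array of 54.1 mg/kg replicate 5 differed in distribution from the 35 others, with a lower quartile of 3.79 (others 3.62 to 3.72) and an upper quartile of 6.94 (others 7.03 to 7.13) on the log2 scale. The median correlation of an array with the 35 others was between 0.993 and 0.995, across probe sets, which are not independent replicates. The 3′ minus 5′ signal of the beta-actin control probe sets, a sign of RNA degradation, was 1.13 ± 0.0758 (SD, n = 6) in vehicle and 1.18 ± 0.0872 at 541 mg/kg on the log2 scale.

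At 541 mg/kg the largest rises were in genes that process or export foreign chemicals. Ces2c, a carboxylesterase, was 2.83-fold higher than in vehicle, at log2 values of 8.84 ± 0.35 against 7.33 ± 0.21 (SD, n = 6; limma adjusted p = 2.46e-08). Abcc3, which encodes an exporter of conjugated organic anions, was 4.42-fold higher (log2 difference 2.14 ± 0.28, adjusted p = 3.53e-05). Ugt2b1, a glucuronosyltransferase, was 2.02-fold higher (1.01 ± 0.13, adjusted p = 3.36e-05). Cyp3a23-3a1, a cytochrome P450 of the CYP3A family, rose by 0.67 ± 0.11 (adjusted p = 0.00102). Of 48 probe sets past the FDR, 36 were higher and 12 lower than in vehicle, in 39 named genes, and 16 differed by at least 1.5-fold. In all 48, named or not, the 6 treated samples lay on 1 side of the vehicle mean, which the test itself favours and the rule for naming genes requires.

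**Figure D1:**
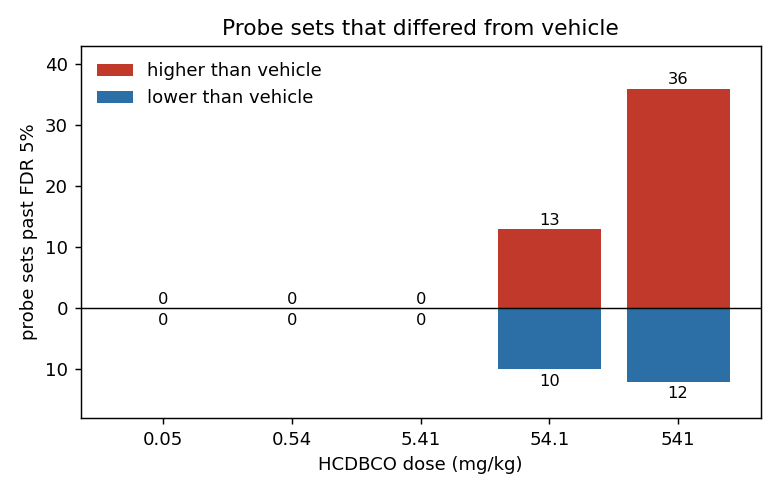
Number of probe sets past an FDR of 5% against vehicle (vertical axis) at each HCDBCO dose in mg/kg (horizontal axis), limma over 36 arrays, with bars above 0 for higher and below 0 for lower expression. No probe set passed at the 3 lowest doses; 13 were higher and 10 lower at 54.1 mg/kg, and 36 higher and 12 lower at 541 mg/kg.

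The fixed list of target genes of the xenobiotic receptors CAR and PXR carried many of these rises. Of its 21 measured members, 9 rose past the FDR over all probe sets and none fell, and 14 rose and 1 fell adjusted over the list alone. Besides Ces2c, Abcc3, Ugt2b1 and Cyp3a23-3a1, these were Cyp2c6v1 (0.34 ± 0.05), Ephx1, the microsomal epoxide hydrolase (0.52 ± 0.10), Aldh1a1, a retinaldehyde dehydrogenase (0.68 ± 0.14), Gsta3, a glutathione transferase (1.34 ± 0.28), and Akr7a3, an aldehyde reductase that detoxifies aflatoxin dialdehyde (0.81 ± 0.17). The list lay above the other genes (camera adjusted p = 1.94e-24, and adjusted p = 1.58e-05 with an estimated correlation). Its mean was 0.56 higher on the log2 scale, with all 6 treated samples above every vehicle sample (exact permutation adjusted p = 0.0165). A probe set annotated to several genes of the Cyp2b subfamily, singled out after its values were seen, was 4.58-fold higher (2.20 ± 0.22, adjusted p = 1.19e-07).

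Other lists of detoxification genes also lay above the rest at 541 mg/kg. Among 22 measured glutathione transferase and glutathione synthesis genes, Gsta3 and Mgst2 (0.35 ± 0.08, adjusted p = 0.0343) rose past the FDR, and 15 rose and 1 fell adjusted over the list alone. Gstt1 was 0.33 higher (adjusted p = 0.0536) and Gstt3 0.79 higher (adjusted p = 0.0931), short of the FDR. The list test gave adjusted p = 7.11e-11, and adjusted p = 0.00675 with an estimated correlation. Of 23 measured target genes of NRF2, a regulator of the response to oxidative and electrophilic stress, Gsta3, Akr7a3 and Ephx1, which are also on the CAR and PXR list, rose past the FDR, and 12 rose adjusted over the list alone (camera adjusted p = 7.34e-10, and adjusted p = 0.0121 with an estimated correlation). Nqo1, a quinone reductase on that list, was 0.69 ± 0.24 higher without passing (adjusted p = 0.315). Of 13 glucuronosyltransferases and sulfotransferases, Ugt2b1 and Sult2a6 (0.93 ± 0.21, adjusted p = 0.0433) rose past the FDR, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.0448 with an estimated correlation). Ugt2b7 (0.39) and Ugt2b35 (0.13) did not pass over all probe sets. Pir (0.69 ± 0.11, adjusted p = 0.00102), which encodes the iron-binding nuclear protein pirin, and Zdhhc2 (0.73 ± 0.13, adjusted p = 0.00356), a palmitoyltransferase, rose outside these lists.

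**Figure D2:**
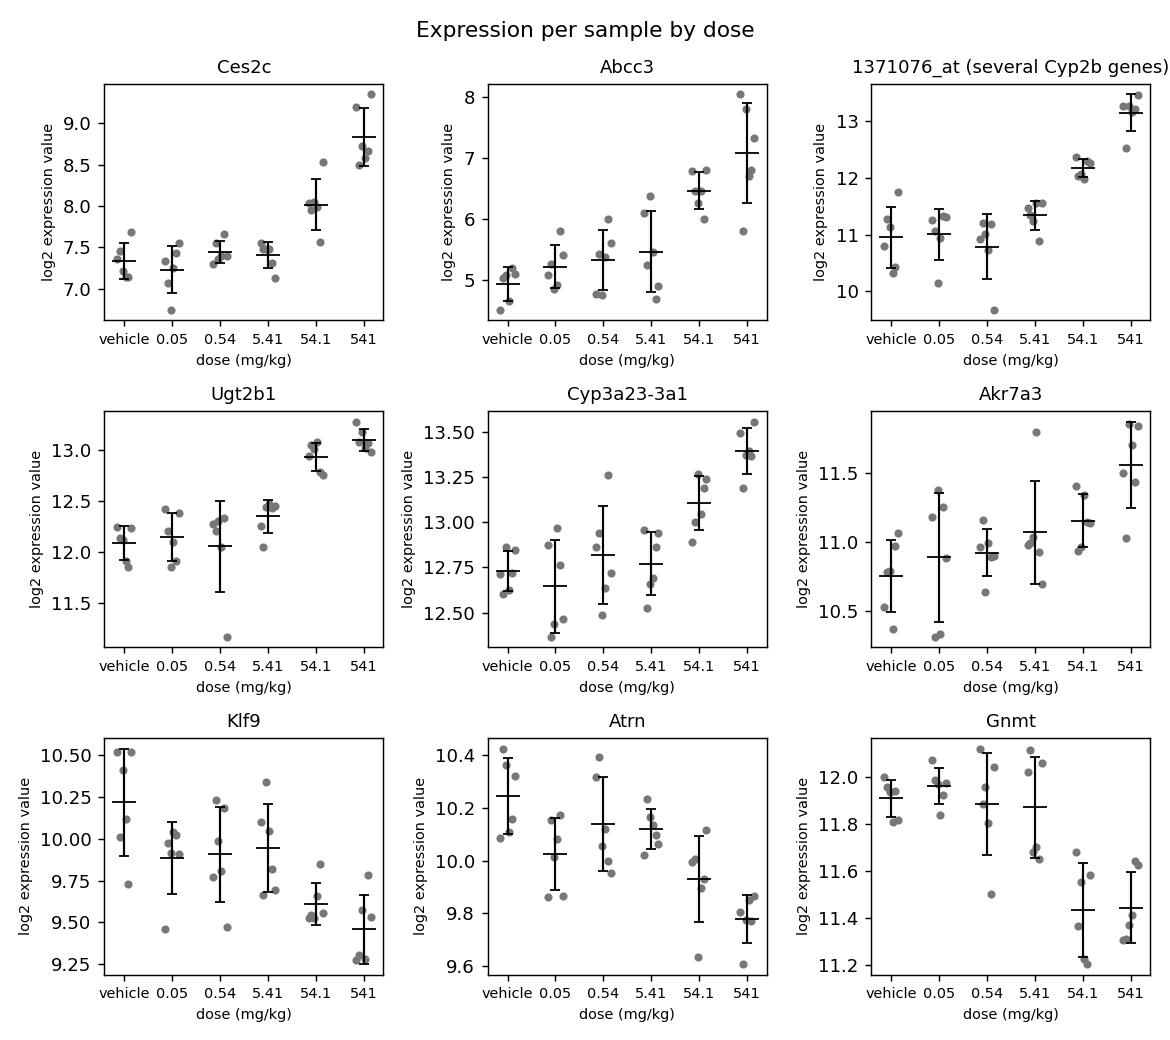
Log2 expression value (vertical axis) by dose in mg/kg (horizontal axis) for 8 named genes and for the probe set of several Cyp2b genes, with 1 point per sample, horizontal marks at the mean and bars of 1 SD, 6 samples per group. The means of Ces2c at vehicle, 54.1 and 541 mg/kg were 7.33, 8.02 and 8.84, and those of Klf9 were 10.22, 9.61 and 9.46.

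Falls at 541 mg/kg were fewer. Klf9, a Krüppel-like transcription factor, fell by 0.76 ± 0.13 (adjusted p = 0.00356). Another of its 3 probe sets was at -0.74 and the dimmest at -0.15, neither past the FDR. Gnmt, glycine N-methyltransferase, fell by 0.47 ± 0.09 (adjusted p = 0.0195). Atrn, attractin, fell by 0.47 ± 0.08 on one probe set (adjusted p = 0.00257) and was at -0.17 on the other (adjusted p = 0.435). Cd320, the transcobalamin receptor (-0.44), Abhd1 (-0.34), Rbm18 (-0.28) and Glud1, the mitochondrial glutamate dehydrogenase (-0.25), made up the other falls taken by the rule. The other probe sets of Abhd1 (-0.15), Rbm18 (-0.30) and Glud1 (-0.23) did not pass (adjusted p = 0.576, 0.332 and 0.0534). Over the 12 probe sets that fell, the mean was already -0.19, -0.18 and -0.20 at the 3 lowest doses, against 0.07, 0.08 and 0.13 for the 36 that rose. Set against the 18 samples of those doses, a choice made after the data had been seen, 3 of the 12 falls and 27 of the 36 rises passed the FDR. The 3 falls were those of Gnmt, Atrn and Abhd1. Klf9, at -0.33, -0.31 and -0.27 against vehicle at the 3 lowest doses, did not pass there, at -0.46 (adjusted p = 0.0564).

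Among lists of liver function at 541 mg/kg, hepatocyte markers lay lower as a group: the mean of 13 members was -0.08, none passed the FDR by itself, and all 6 treated samples lay below every vehicle sample (camera adjusted p = 0.00408, adjusted p = 0.0448 with an estimated correlation, exact permutation adjusted p = 0.0165). Apoa1 (-0.17), the main protein of high-density lipoprotein, and Tat (-0.47), tyrosine aminotransferase, had its smallest p-values. Of the 12 camera calls at this dose 5 held with an estimated correlation, those given so far; the rest did not. Proteasome subunits were higher in 25 of 26 members, 12 of them adjusted over the list alone and none over all probe sets, with Psmb7 at 0.24 and Psmd14 at 0.25, and at 0.18 and 0.05 on its other probe sets (adjusted p = 5.21e-12, and adjusted p = 0.109 with an estimated correlation). Of 21 lipoprotein and lipid transport genes, 4 had higher means than in vehicle, 4 fell adjusted over the list alone and none over all probe sets, with the triglyceride regulator Apoa5 at -0.21 (adjusted p = 1.86e-05, and adjusted p = 0.0928 with an estimated correlation). All 11 endothelial cell markers had lower means, led by Stab2 (-0.27) and Stab1 (-0.30), scavenger receptors of sinusoidal endothelium, and none passed either adjustment (adjusted p = 4.2e-05, and adjusted p = 0.152 with an estimated correlation). Of 19 urea cycle and amino acid breakdown genes, Glud1 fell past the FDR, and 6 fell and 1 rose adjusted over the list alone, with Hal at -0.36, Oat at -0.49 and Ddc at 0.29, or 0.12 on its other probe set (adjusted p = 0.00041, and adjusted p = 0.248 with an estimated correlation). Of 12 glucose production and fasting genes, 1 fell adjusted over the list alone, the glucose transporter Slc2a2 at -0.25 (adjusted p = 0.00497, and adjusted p = 0.109 with an estimated correlation). Of 9 genes higher in female than in male rat liver, Abcc3 passed the FDR and Cyp2c12 was at 0.68 (adjusted p = 0.00621, and adjusted p = 0.152 with an estimated correlation). Periportal hepatocyte genes, led by Hal and Ass1 (-0.22), gave adjusted p = 0.02, and adjusted p = 0.248 with an estimated correlation.

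**Figure D3:**
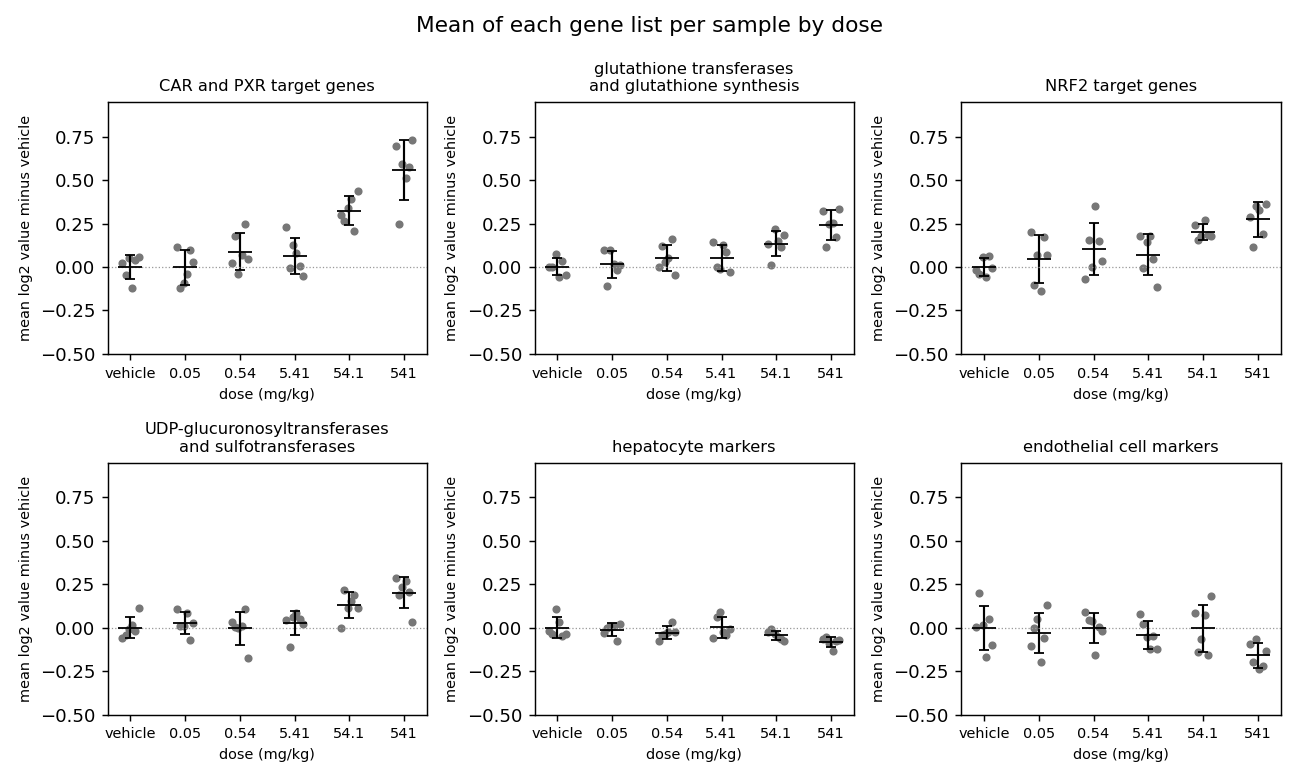
Mean log2 value of the members of 6 fixed gene lists minus the vehicle mean (vertical axis) by dose in mg/kg (horizontal axis), with 1 point per sample, horizontal marks at the group mean and bars of 1 SD, 6 samples per group. The mean of the CAR and PXR target genes was 0.32 at 54.1 mg/kg and 0.56 at 541 mg/kg; that of the endothelial cell markers was -0.16 at 541 mg/kg.

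The other 26 lists gave camera adjusted p-values between 0.0666 and 0.908 at 541 mg/kg. They were AhR, PPAR-alpha and p53 target genes, cholesterol synthesis, fatty acid synthesis, bile acid synthesis and transport, thyroid hormone response, genes higher in male rat liver, cell cycle, unfolded protein response, heat shock, acute phase proteins, complement and coagulation, circadian clock, oxidative phosphorylation, metallothioneins and iron handling, pericentral genes, and markers of Kupffer, stellate, bile duct, T, B, neutrophil, erythroid, pancreatic and fat cells. The bile acid list had a median of -0.08 and a mean of 0.0042, and its test pointed down. In the thyroid hormone list Ugt2b1 rose and Klf9 fell. Of the genes given at every dose whatever their values, the following passed at neither 54.1 nor 541 mg/kg, with values given in that order. Cyp1a1, a target of the aryl hydrocarbon receptor, was at 0.41 and 0.37, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.23 and 1.09, and Cyp4a1, a PPAR-alpha target, at 0.11 and -0.14. Cyp1a2 was at 0.04 and -0.05, Nqo1 at 0.60 and 0.69, the deiodinase Dio1 at -0.04 and -0.18, the hormone Fgf21 at -0.39 and -0.93, the cell cycle inhibitor Cdkn1a at -0.40 and -0.07, with its dimmer probe set at -0.45 and -0.35, and the proliferation marker Mki67 at 0.08 and 0.26. The count of 48 at 541 mg/kg depended on single samples: it was 25 without vehicle replicate 4, 21 without 541 mg/kg replicate 1 and 18 without 541 mg/kg replicate 4. Of the 48, 17 passed in all 12 fits that left out 1 of the samples compared, Ces2c, Abcc3, Ugt2b1 and Cyp3a23-3a1 among them. Aldh1a1 passed in 6 of the 12, Gsta3, Akr7a3 and Mgst2 in 5 each and Sult2a6 in 1. For 541 mg/kg against vehicle the count was 83 with the filter on dim probe sets, 80 with array quality weights and 31 with only these 2 groups in the fit.

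At 54.1 mg/kg 23 probe sets passed, 13 higher and 10 lower, in 19 named genes. The largest rises were again in Abcc3 (2.88-fold, log2 difference 1.53 ± 0.28, adjusted p = 0.0173), Ugt2b1 (1.80-fold, 0.85 ± 0.13, adjusted p = 0.00219) and Ces2c (1.61-fold, 0.68 ± 0.14, adjusted p = 0.0323), and the probe set of several Cyp2b genes was 2.33-fold higher (adjusted p = 0.0173). Me1, the cytosolic malic enzyme, rose by 0.52 ± 0.11 (adjusted p = 0.0381) and by 0.75 on its other probe set. Smaller rises were in Secisbp2l (0.39), Dync2h1, a dynein heavy chain (0.34), Nsdhl, an enzyme of cholesterol synthesis (0.32), Kyat1, a kynurenine aminotransferase (0.32), Saysd1 (0.31) and Gpr15lg (0.29). The dimmer probe sets of Secisbp2l (0.22) and Nsdhl (0.23) did not pass (adjusted p = 0.567 and 0.216). Falls were in Ccdc126 (-0.68), Tmx4 (-0.53, with its dimmer probe set at 0.06), Hexim1, an inhibitor of transcription elongation (-0.48, adjusted p = 0.00219), Gnmt (-0.48), Crip2 (-0.39) and Itgb3, an integrin subunit (-0.33). Several of these were also below vehicle at the 3 lowest doses without passing there, with Ccdc126 at -0.40, -0.50 and -0.52 and Tmx4 at -0.26, -0.33 and -0.37. Set against the 18 samples of those doses, also a choice made after the data had been seen, 1 of the 10 falls, Gnmt, and 4 of the 13 rises, those of Ugt2b1, Ces2c, Cyp2c6v1 and the probe set of several Cyp2b genes, passed the FDR. Abcc3 did not, at 1.12 (adjusted p = 0.0655). Nor did Kyat1 at 0.25 (adjusted p = 0.0655), Dync2h1 at 0.28 (adjusted p = 0.0714) or Ccdc126 and Tmx4 at -0.21 each (adjusted p = 0.849 and 0.772).

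The CAR and PXR target genes were the one list whose call at 54.1 mg/kg held with an estimated correlation: 4 of 21 rose past the FDR, and 10 rose and 1 fell adjusted over the list alone (adjusted p = 2.26e-08, and adjusted p = 0.027 with an estimated correlation). The call was lost for 7 others: urea cycle and amino acid genes, lower (adjusted p = 8.16e-06, and adjusted p = 0.263 with an estimated correlation), NRF2 targets, higher, with Me1 past the FDR (0.000107 and 0.263), cholesterol synthesis, higher, with Nsdhl past the FDR (0.000162 and 0.697), glutathione genes, higher (0.000563 and 0.263), proteasome subunits, higher (0.00105 and 0.783), lipoprotein genes, lower (0.00184 and 0.368), and genes higher in female liver, with Abcc3 past the FDR (0.0265 and 0.368). The count of 23 was 5 without vehicle replicate 1, 7 without 54.1 mg/kg replicate 4, 14 without vehicle replicate 6 and 15 without vehicle replicate 5 or any of 54.1 mg/kg replicates 1, 2 and 3. It was 36 without vehicle replicate 2 and 35 without 54.1 mg/kg replicate 5. In all 12 such fits 3 probe sets passed, those of Ugt2b1, Hexim1 and Gpr15lg. Abcc3 passed in 11 of the 12, Ces2c in 3 and the brighter probe set of Me1 in 2. Centring each array on its median gave 7 higher and 10 lower. For 54.1 mg/kg against vehicle the count was 64 with array quality weights, 43 with only these 2 groups in the fit and 37 with the filter on dim probe sets.

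Of the calls at the 2 highest doses, 8 were shared, 6 higher and 2 lower, where independent lists would share 0.0151 and 0.00387. Besides Ces2c, Abcc3, Ugt2b1, Gnmt and Cyp2c6v1 they were the dimmer probe set of Me1, 1 of 6 probe sets of Crem, a cAMP-responsive transcription factor, and that of several Cyp2b genes, the last 3 named after their values were seen. At 541 mg/kg the brighter probe set of Me1 was at 0.43 and the other 5 of Crem were between -0.41 and -0.18, none past the FDR. Every probe set called at either dose differed in the same direction at the other. Both comparisons use the same vehicle samples. The log2 differences at the 2 doses correlated with r = 0.70 across probe sets, which are not independent replicates. Unchanged groups simulated against shared controls gave 0.503 on average (95% of 100 simulations from 0.28 to 0.696). The share of all probe sets with the same sign at both doses was 71.6%, within the simulated range (66.6% on average, 59.0% to 73.7%). The covariance was 0.0107 against 0.00519 simulated. With 3 vehicle samples for each dose, the correlation was 0.309 on average over 20 splits (0.189 to 0.422). Simulated without effect it was 0.0115 (95% of 100 simulations from -0.240 to 0.270), a range that overlaps the lower splits. In these splits 0 to 4 calls were shared, but fewer probe sets passed at all, on average 4.65 at 54.1 mg/kg and 15 at 541 mg/kg. None of the simulations shared a call, but their groups held no changes. They cannot show how many calls shared vehicle samples alone would add between 2 groups with real changes.

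Between 541 and 54.1 mg/kg directly, Ces2c was the one probe set past the FDR, 0.82 ± 0.14 higher at 541 mg/kg (adjusted p = 0.0294). Abcc3 was 0.62 ± 0.28 higher and Cyp3a23-3a1 0.29 ± 0.11 higher without passing (adjusted p = 0.999 and 0.969). The CAR and PXR list was higher at 541 mg/kg, by 0.24 on average (adjusted p = 6.8e-10, and adjusted p = 0.0111 with an estimated correlation), and of 12 camera calls it was the 1 that held with the estimate. The others had adjusted p from 0.178 to 0.858 with an estimated correlation, endothelial cell markers, lower at 541 mg/kg, among them. The Ces2c call was absent without any 1 of 54.1 mg/kg replicates 1 to 5 or of 541 mg/kg replicates 1, 3 and 6, and 2 probe sets passed without 541 mg/kg replicate 4.

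No probe set passed at 0.05, 0.54 or 5.41 mg/kg with limma. At an unadjusted p under 0.05 there were 939, 1297 and 1498 probe sets, fewer than the 1552.1 that chance gives. An unmoderated test also gave 0 at each. Ces2c was at -0.10, 0.11 and 0.07 at these doses, Abcc3 at 0.29, 0.39 and 0.53, and Ugt2b1 at 0.06, -0.03 and 0.26, with 0.977 as the lowest adjusted p. Of the lists, Kupffer cell markers at 0.05 mg/kg (11 of 12 members higher, adjusted p = 0.000177, and adjusted p = 0.972 with an estimated correlation), cholesterol synthesis, cholangiocyte and T cell markers at 0.54 mg/kg, all higher (0.000916, 0.00554 and 0.0277, and with an estimated correlation adjusted p = 0.787, 0.739 and 0.739), and urea cycle genes at 5.41 mg/kg, lower (0.0266, and adjusted p = 0.887 with an estimated correlation) passed with the preset correlation alone.

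Over the whole dose order, 222 probe sets passed the FDR for a linear contrast of the group means, 106 upward and 116 downward, in 170 named genes. Which direction was the more frequent depended on the scaling, with 143 upward and 125 downward after cyclic loess and 73 and 99 after centring each array on its median. The slope per dose step was 0.28 for Ces2c (adjusted p = 1.43e-09), 0.42 for Abcc3 (adjusted p = 1.19e-06), 0.22 for Ugt2b1 (adjusted p = 6.45e-08), -0.13 for Klf9 (adjusted p = 0.00179) and -0.11 for Gnmt (adjusted p = 0.000103). The trend calls held 47 of the 48 probe sets called at 541 mg/kg and 19 of the 23 called at 54.1 mg/kg, and 164 called at neither. Group means rose or fell at every step in 38 of them, where a random order of 6 means does so in 0.278%, and the trend test itself selects for such an order. The F-test gave 31 probe sets, all of them among the trend calls and 27 among those at 541 mg/kg. The count of the dose trend was 85 without 541 mg/kg replicate 1, 105 without 541 mg/kg replicate 4, 127, 130 and 144 without vehicle replicates 3, 5 and 1, and 141 without 0.05 mg/kg replicate 6 or 541 mg/kg replicate 5. It was 376 with array quality weights and with the filter on dim probe sets. In alternatives chosen after seeing the data, it was 15 without the 541 mg/kg group and 45 in dosed groups only. For any difference among the 6 groups the count was 53 with array quality weights, 17 without any 1 of 541 mg/kg replicates 1, 3, 4 and 6, and 20 without 54.1 mg/kg replicate 3.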

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

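The cyclic loess test of the array below and the counts over other splits of the samples were chosen after the results had been seen. In groups of 6 samples, 369 sets of values (107 genes, 13 lists and 3 array measures in vehicle, 54.1 and 541 mg/kg) were searched for a sample far from the 5 others; 20 had one, where chance, at about 1 in 20, gives 18.45.

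The array of 54.1 mg/kg replicate 5 lay farthest from its group mean, with a root mean square distance of 0.200 against 0.147 ± 0.00954 (mean and SD) for the 5 others. Differences in intensity left by the normalisation are a candidate explanation. After cyclic loess the distance was 0.177 against 0.146 ± 0.0089, and its gap to the next array went from 0.633 to 0.496 of the range of the 6 arrays. Since 58.8% of the excess distance remained and the array was still the farthest, this test leaves open whether normalisation accounts for it. No biological explanation was tested.

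For genes that passed at 541 mg/kg, the lone samples were as follows, as log2 values beside the mean of the 5 others. Sult2a6 was 8.71 in vehicle replicate 1 beside 9.50. Zdhhc2 was 6.01 in 54.1 mg/kg replicate 6 beside 6.73, and 6.62 in 541 mg/kg replicate 5 beside 6.97. In 541 mg/kg replicate 2, Aldh1a1 was 11.88 beside 12.47 and Atrn 9.61 beside 9.81. Abhd1 was 8.76 in vehicle replicate 2 beside 8.63. Mgst2 was 11.68 in 541 mg/kg replicate 6 beside 11.39. For genes that passed at 54.1 mg/kg, Gpr15lg was 3.74 in 54.1 mg/kg replicate 5 beside 3.55, and Crip2 was 10.53 in vehicle replicate 4 beside 10.81.

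Among genes that passed at neither dose, Cpt1a was 11.01 beside 10.30 and Sc5d 11.34 beside 10.99 in vehicle replicate 3. Cyp2c12 was 11.83 in 541 mg/kg replicate 1 beside 12.04, and Abcg8 was 5.08 in 541 mg/kg replicate 2 beside 6.62. Stab2 was 8.20 in 541 mg/kg replicate 4 beside 8.63. In 54.1 mg/kg replicate 5, Vldlr was 5.95 beside 5.43 and Dio1 6.97 beside 7.33. Uqcrc1 was 11.43 in 54.1 mg/kg replicate 1 beside 11.22, and Lrat was 8.66 in vehicle replicate 1 beside 8.42. The mean of the glucose production and fasting genes was -0.35 in vehicle replicate 5 beside 0.07, relative to the vehicle mean.

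Ces2c differed between the 2 highest doses, by 0.82 in the direct test of 541 against 54.1 mg/kg. Other splits of the samples did not exclude chance for that count: 6 of 100 splits of the 12 samples gave at least as many probe sets as the real 1, and the highest other split gave 3. Of 100 splits, only the real one reached the count of 23 at 54.1 mg/kg (highest other 3) or of 48 at 541 mg/kg (highest other 4). Of 100 allocations of the 36 samples, only the real one reached the 222 of the dose trend (highest other 1) or the 31 of the F-test (highest other 2). These tests argue against chance for the counts, no finer than 1 in 100, and do not settle any single call. The counts at 54.1 and 541 mg/kg also share their vehicle samples. At the 3 lowest doses this comparison could decide nothing, since any split gives at least the real 0 calls. The highest other counts there were 0, 1 and 5.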

How the results depend on the processing

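The trends over dosed groups or up to 54.1 mg/kg and the comparisons with low-dose samples as controls were added after the data had been seen; the other alternatives were planned. At 0.05, 0.54 and 5.41 mg/kg the limma count stayed at 0 under every alternative run, with 939, 1297 and 1498 probe sets at an unadjusted p under 0.05. Fewer tests and brighter signal came with a filter that kept probe sets above the median level: the counts were 37 for 54.1 mg/kg against vehicle, 83 for 541 mg/kg against vehicle and 376 for the dose trend, and all main calls that passed the filter stayed (21 of 21 and 47 of 47). For the rest the cause was not tested. With array quality weights the counts were 64, 80 and 376, and 53 for any difference among the 6 groups, with all 23 and 48 main calls among them. With only the 2 groups compared in the fit, which leaves fewer samples for the spread, they were 43 at 54.1 and 31 at 541 mg/kg. The unmoderated test gave 0 for 541 mg/kg against 54.1 mg/kg. With the 3 lowest doses as controls, 5 probe sets passed at 54.1 mg/kg, all among the 23, and 84 at 541 mg/kg, 30 of them among the 48. The dose trend gave 45 in dosed groups only and 15 up to 54.1 mg/kg. With 3 vehicle samples for each dose, the correlation of the 2 highest doses was 0.189 to 0.422.

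Leaving out 1 sample, the counts ranged from 5 to 36 for 54.1 mg/kg against vehicle, from 18 to 63 for 541 mg/kg against vehicle, from 0 to 2 for 541 mg/kg against 54.1 mg/kg, from 85 to 272 for the dose trend and from 17 to 41 for any difference among the 6 groups; the highest at 541 mg/kg was without its replicate 2. Across all probe sets, same-numbered samples showed little shared deviation: 6 of 30 pairs of a vehicle and a dosed sample correlated above 0.1 (from -0.212 to 0.154). Of 36 samples, 5 were closest to their own number, where chance gives 6. The 3′ minus 5′ signal of the GAPDH control probe sets did partly follow the number. It was highest in replicates 2 and 6 in every group except 541 mg/kg, for example 0.0598 and -0.0532 at 0.05 mg/kg. At 541 mg/kg it was highest in replicate 5 (0.0933). A deviation shared by number was thus not excluded, and its cause was not tested. With the replicate block the counts were 28 at 54.1 mg/kg, 22 of the 23 kept, 44 at 541 mg/kg, 39 of the 48 kept, 212 for the trend, 28 for the F-test and 1 for 541 against 54.1 mg/kg.

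No named gene or list changed direction past the threshold under any alternative run. With an estimated correlation 19 of 190 list results lost their call, though most of the 190 had no call to lose. At 54.1 mg/kg 1 of 8 list calls held, at 541 mg/kg 5 of 12, and none at the 3 lowest doses. Leaving out 1 sample ended the call in 312 of 3312 gene results, many of them without a call to lose, and brought it in 16. In all 12 fits that left out a compared sample, 3 of the 23 calls at 54.1 mg/kg and 17 of the 48 at 541 mg/kg held. Signal over background limits dim probe sets: the filter left out 2 of the 23 calls at 54.1 mg/kg, and Gpr15lg, at a mean of 3.44, lay below the lower quartile of the arrays, whose median was 3.68.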

Other observations

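The test of held-out vehicle samples and the cyclic loess test of the 12 falls were set before their results were seen; the other tests in this part were chosen afterwards.

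Some members of lists that did not pass had large mean differences that single out candidates for follow-up rather than changes. Scd, the stearoyl-CoA desaturase, was at -1.15 at 54.1 mg/kg and -1.11 at 541 mg/kg (adjusted p = 0.327 and 0.315). Hamp, which encodes the iron-regulating hormone hepcidin, was at -0.40 and -0.72 (adjusted p = 0.544 and 0.147), lower than the vehicle mean in all 6 samples at both doses. Xbp1, a transcription factor of the unfolded protein response, was at -0.51 and -0.53 (adjusted p = 0.198 and 0.147). Bhlhe40, a repressor linked to the clock, was at -0.81 and -0.53 (adjusted p = 0.299 and 0.554). The carnitine palmitoyltransferase Cpt1a was at 0.12 and -0.37 (adjusted p = 0.834 and 0.335), with its dimmer probe set at -0.09 and -0.48. Part of the Cpt1a difference at 541 mg/kg comes from vehicle replicate 3, at 11.01 beside a mean of 10.30 for the 5 others. The pericentral genes Glul, glutamine synthetase, and Slc1a2, a glutamate transporter, were at -0.31 and 0.34 at 541 mg/kg (adjusted p = 0.233 and 0.253), with the dimmer probe sets of Glul at -0.50 and -0.34 and that of Slc1a2 at 0.04. Ccnd1, cyclin D1, was at -0.60 there and Pnlip, pancreatic lipase, at 0.33 (adjusted p = 0.223 and 0.0688), with the dimmer probe sets of Ccnd1 at -0.48 and -0.47.

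At 541 mg/kg the exact permutation test of list means adds 1 call to those that held with an estimated correlation, and that call rests on Abcc3. The mean of the 9 genes higher in female rat liver was 0.31 above vehicle at 54.1 mg/kg (adjusted p = 0.0274) and 0.36 above at 541 mg/kg (adjusted p = 0.0165), while their median difference was 0.07 at both doses. Without Abcc3, which is also on the CAR and PXR list, the mean of the other 8 was 0.16 and 0.14 above vehicle, with 5 of 6 treated samples above the vehicle mean at each dose, and the call ended (exact permutation adjusted p = 0.283 and 0.221). NRF2 targets were 0.20 higher at 54.1 mg/kg by the same exact permutation test (adjusted p = 0.0274), though their camera call at that dose was lost with an estimated correlation. AhR targets were 0.13 higher at 541 mg/kg without passing (exact permutation adjusted p = 0.0705).

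The 12 probe sets lower at 541 mg/kg already differed from vehicle at the 3 lowest doses, by a median of -0.21, and the median share of their difference at 541 mg/kg already present there was 45.6%. A response complete at the lowest dose is argued against, since their mean at 54.1 mg/kg was lower than at the 3 lowest doses by -0.210 (exact permutation p = 1.49e-05), and so are array-wide intensity differences, since cyclic loess left 94.5% of the median. High vehicle values by chance remain possible. Probe sets chosen with 3 vehicle samples differed at the low doses by -0.0900 from the 3 held out (range over 20 splits -0.202 to -0.00994). They differed by -0.246 from the 3 used. Groups simulated without effect gave falls a share of 48.7% (34.2% to 64.6%). Those groups held no change at 541 mg/kg, so their share is no measure for calls that may hold a real change. For the 36 rises the observed share was 15.1%, and the differences were 0.0242 from the vehicle samples held out and 0.115 from those used. RNA degradation cannot be told apart, because the beta-actin covariate, which left 99.4%, moved probe sets by a median of 0.00141 only, its 3′ minus 5′ signal being 1.13 ± 0.0758 (SD) in vehicle and 1.14 ± 0.112, 1.13 ± 0.0701 and 1.11 ± 0.0562 at the 3 lowest doses, and a real effect of the low doses stays open: a limma fit of those 18 samples and vehicle gave 0 probe sets past the FDR and 1421 at an unadjusted p under 0.05 (0 and 1312 with all 36 samples), and 60 of 100 splits in that smaller fit gave as many of the latter (highest other 3111).

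All 11 measured endothelial cell markers had lower means at 541 mg/kg, by -0.158 on average (vehicle SD 0.126, 541 mg/kg SD 0.0713; exact permutation p = 0.0238, adjusted p = 0.0987 over 38 lists). A smaller share of all non-hepatocyte cells stays open: the endothelial mean minus that of the 6 other lists of such cells was -0.209, with an exact permutation p of 0.0628 that counts the choice of the lowest of 7 lists. Those lists were at 0.02 ± 0.15 (SE) for Kupffer cells, -0.02 ± 0.15 for stellate cells, 0.07 ± 0.05 for cholangiocytes, 0.10 ± 0.05 for T cells, 0.06 ± 0.06 for B cells and 0.09 ± 0.07 for neutrophils. Cholangiocyte, T cell, B cell and neutrophil markers thus showed no fall, while those of Kupffer and stellate cells were too variable to tell. Several of the former were dim, with mean log2 values of 3.76 for Krt7, 4.25 for Gzmb, 3.10 for Cr2 and 3.14 for Il1r2, though 8.82 for Epcam. A fall in such dim markers could be missed. Hepatocyte markers were at -0.08 ± 0.03 (SE). How far a smaller share of other cells would raise them was not estimated and may lie within that spread. Their value therefore decides nothing about that explanation. Leaving out the sample that carried most of the endothelial difference left -0.119, and cyclic loess left 95.2%, which argue against 1 sample or array-wide intensity as the whole cause. Chance stays open, since neither the permutation test adjusted over 38 lists nor camera with an estimated correlation (adjusted p = 0.152) passed, and no biological explanation was tested.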
